A study of Mus musculus with 6 samples.

How the data were processed

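The values came from a pair of whole-series tables, of expected counts and of TPM, each with 55291 gene symbols and a column for each of the 6 libraries. The expected counts, as deposited, are RSEM estimates of the fragments from each gene, and 7.16% of them are not whole numbers. The TPM values, as deposited, are relative transcript abundances, in which each expected count was divided by the gene's effective length and scaled to the same sum in each library. The submitters' processing notes name RSEM, DESeq2 1.28.1 and the mm10 mouse genome without giving the role of each. The aligner and the annotation release were not given in the sources used here. Total RNA was sequenced in pairs on a DNBSEQ instrument.

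The columns of both tables carry the names WT-1 to WT-3 and KO-1 to KO-3. WT is the genotype label of the control samples, so WT-1 to WT-3 were taken as shCtrl_1 to shCtrl_3 by the number in the sample title. KO matches no label in these letters, but the samples have only 1 other genotype label, a knock down of USP8, so KO-1 to KO-3 were taken as shUSP8_1 to shUSP8_3. The Usp8 counts of each library check this match for groups, not for numbers within a group. Transcript identifiers linked the symbols to GENCODE M21 (GRCm38), in which 141374 of 142604 transcripts (99.14%) were found.

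Expected counts were rounded and tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr (minimum count 10, minimum total 15) and a robust quasi-likelihood F test of shUSP8 against shCtrl. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SE is the absolute fitted log2 fold change divided by the square root of the quasi-likelihood F statistic, not the standard error of the coefficient. It can be too small for large changes with few counts in a group. CPM values use TMM factors. Gene lists were written from general knowledge, 37 in all, and the 34 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with the preset correlation of 0.01. Camera with a correlation estimated from the data, camera on ranks and fry were run beside it. Group shares were compared with a two-sided exact permutation test over all splits of 3 against 3. Mean fragment length came from a straight-line fit of expected count over TPM, which is proportional to effective length, against transcript length in genes with a single transcript. Other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

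The comparison, the lists, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Usp8, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap of the groups, up to 4 called members of each list by smallest p (or the 2 highest in CPM where none was called), and 9 genes chosen in advance: Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp, Atp6v0d2, Ppargc1b, Tfam and Pink1. Predicted genes and clone names were passed over, and some genes that the rule selects are not reported. Members named outside this rule were chosen after their values were seen. Effective-length offsets, in which each gene's expected count over TPM entered edgeR as an offset (available for 11702 genes), were added after fragment lengths had been seen.

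Alternatives covered normalisation (RLE, upper quartile, library totals), the filter, DESeq2, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), counts left unrounded, the mitochondrial genome left out, a replicate block and each library left out. Equal replicate numbers were not taken as pairs, since the labels do not call them so. The chi-square per gene between shCtrl_1 and shCtrl_2 was 1.87, against 3.67 to 12.3 in the other pairs within a group.

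The pipeline was tested on simulated data with 12440 genes, 200 of them changed, in 5 draws. edgeR recovered 19.2% of genes changed 1.2-fold, 76.8% at 1.5-fold, 84.8% at 2-fold and 95.6% at 4-fold, and 3.8% of its calls were false. The real comparison called 4077 genes, far more than the 200 changed here, so these shares need not carry over to it. False calls were 3.9% with DESeq2, 3.9% with limma-voom and 15% with limma-trend on log2(TPM + 1). For that scale, counts drawn without a length effect were divided by the real effective lengths, which differ between libraries. The false calls on TPM could therefore come from the draws themselves and do not measure the method on the real libraries. With the spread of each gene as fitted, 8.2% of edgeR calls were false. With the observed fragment lengths, recovery in edgeR was 4%, 54%, 76% and 90% and 8% of calls were false. Offsets raised recovery to 22.4%, 80%, 87.2% and 95.6%, with 5.8% false. These offsets were the factors used to draw the counts, so the gain was built in. It does not show how well offsets correct the real libraries. Lists were tested apart from these 5 draws, in a single draw for each setting, with the shifted lists all moved upward. Camera with the preset correlation called 16 of 20 lists of 30 genes shifted by 0.1 and 20 of 20 shifted by 0.3. It also called 1 of 80 unshifted lists beside the smaller shift. With an estimated correlation it called 20 of 20 at 0.3 and missed all 20 at 0.1, and fry called 6 and 20, with 2 of 80 unshifted lists called beside the larger shift. Fragment lengths alone, in a single draw with no gene changed, led to no call among the 34 lists. All genes were drawn independently, so the members of a list were not correlated. The draws therefore cannot show how camera or fry perform on real lists with correlated members.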

Results

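RNA sequencing covered 6 libraries of RAW264.7 cells, a mouse macrophage-like line raised from ascites that fuses into bone-resorbing osteoclasts when given RANKL, the cytokine that drives osteoclast formation. All cultures had received RANKL at 50 ng/mL for 4 days. The shCtrl group (n = 3) carried a control short hairpin and the shUSP8 group (n = 3) carried a hairpin against Usp8, which encodes a deubiquitinating enzyme of endosomes. The series title places the study in mitochondrial regulation by USP8 in osteoclasts, and the comparison asks which transcripts differ when Usp8 is reduced during osteoclast formation. Total expected counts were 20121644, 20133424 and 20213939 in shCtrl_1 to shCtrl_3 and 20142107, 20063482 and 19973522 in shUSP8_1 to shUSP8_3. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

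Usp8 fell 4.00-fold on average, and every shUSP8 library lay below every shCtrl library. The gene lies on chromosome 2 at 126707328 to 126759297, plus strand (GRCm38). Expected counts were 2785, 2561 and 2645 in the shCtrl libraries and 656, 720 and 718 in the shUSP8 libraries. Its level dropped from 135.7 ± 5.86 to 33.9 ± 1.68 CPM (SD, n = 3 per group), a log2 fold change of -2.00 (SE 0.06; edgeR adjusted p = 1.47e-10). Across genes, the Pearson correlation of log2 CPM was 0.993 to 0.994 between shCtrl libraries, 0.987 to 0.992 between shUSP8 libraries and 0.970 to 0.974 between groups; genes are not independent replicates. The first principal component held 67.2% of the variance and separated the groups. The second held 13.1% and lay mainly between shUSP8_1 and shUSP8_2.

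**Figure D1:**
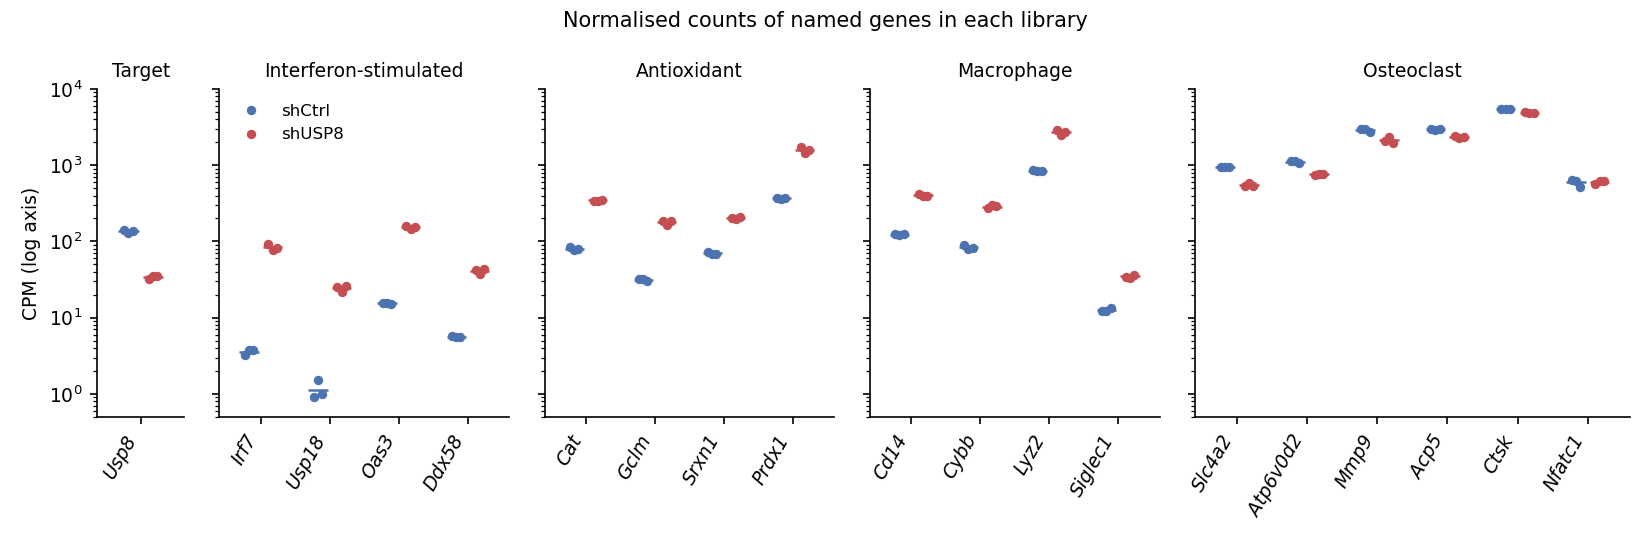
Normalised counts (CPM, log axis) of named genes in the 3 shCtrl and 3 shUSP8 libraries; each point is 1 library and each line is a group mean. Usp8 lies at 135.7 CPM on average in shCtrl and 33.9 CPM in shUSP8, the interferon-stimulated, antioxidant and macrophage genes lie higher in every shUSP8 library, and Nfatc1 overlaps between the groups.

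Reduced Usp8 came with a broad change in the transcriptome: of 12440 genes tested, 2218 rose and 1859 fell (edgeR, adjusted p under 0.05), and 557 rose and 108 fell at least 2-fold. Among expressed genes (mean log2 CPM of at least 3) whose groups did not overlap, the largest rise was that of Rtp4, a chaperone of odorant and opioid receptors induced by interferon. Its expected counts were 7, 5 and 2 in shCtrl, and its mean was 16.2 ± 2.85 CPM in shUSP8 (log2 fold change 6.05, SE 0.25). Irf7, a transcription factor of the interferon system, rose from 3.57 ± 0.283 to 84.3 ± 6.68 CPM (log2 fold change 4.56, SE 0.09, adjusted p = 9.82e-12). Mmp12, the macrophage elastase, rose from 5.32 ± 0.909 to 105.7 ± 8.99 CPM. Clec4n, which encodes a fungal receptor, rose from 3.03 ± 0.416 to 54.7 ± 3.58 CPM. Slpi, a secreted inhibitor of neutrophil elastase, rose by a log2 fold change of 5.16, Adh7, an alcohol dehydrogenase that oxidises retinol, by 4.79, and Ptpn14, a tyrosine phosphatase, by 4.68. Usp18, a protease that removes ISG15 from proteins, rose by 4.42, Treml4, a myeloid receptor, by 4.35, and Procr, the protein C receptor, by 4.12.

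Among the falls, Tubb2b, a beta-tubulin, went from 22.1 ± 2.36 to 4.04 ± 0.476 CPM (log2 fold change -2.45, SE 0.12, adjusted p = 1.16e-08). Its value was -1.80 with effective-length offsets. Rgs16, a brake on G protein signals (-1.86), and Ankrd2, a stretch-responsive ankyrin protein (-1.67), fell. Sorbs2, an adaptor of the actin cytoskeleton (-1.50), Npl, a sialic acid lyase (-1.40), and Sema7a, a membrane-anchored semaphorin (-1.23), fell as well. The histone genes H2bc21 (-1.23) and H3c15 (-1.22) fell too; histone genes exist in near-identical copies, so their counts are uncertain. Tpm2, a tropomyosin, had the lowest fitted value in this set (-2.61, SE 0.65, adjusted p = 0.0449), with expected counts of 469, 453 and 553 in shCtrl and 178, 43 and 31 in shUSP8. Its call was lost without shCtrl_1 (adjusted p = 0.123), shCtrl_2 (0.128), shCtrl_3 (0.124), shUSP8_2 (0.105) or shUSP8_3 (0.0956). The Tpm2 call was also lost with the replicate block (adjusted p = 0.142) and without the filter on low counts (0.075). The share of changed genes that rose was 54.4% with TMM factors, 72.6% with library totals alone and 82.6% on log2(TPM + 1), a scale on which the median of all genes lay 0.12 higher in shUSP8.

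Interferon-stimulated genes were the group with the largest change. Of 34 members, 27 passed the count filter, and all 27 rose, over all genes tested and adjusted over the list alone. Their median log2 fold change was 2.95 (camera adjusted p = 4.87e-22, and adjusted p = 0.138 with an estimated correlation). Some members passed the filter only through their counts in shUSP8, so for them a rise was a condition of testing. An example, named after the values were seen, was Ifit1, with expected counts of 6, 3 and 1 in shCtrl. Oas3, which makes the signal that activates RNase L, rose from 15.3 ± 0.263 to 153.6 ± 8.62 CPM (log2 fold change 3.32, SE 0.06, edgeR adjusted p = 5.64e-12). Ddx58, the RNA sensor RIG-I, rose from 5.62 ± 0.137 to 41.1 ± 3.16 CPM, and Usp18 from 1.14 ± 0.331 to 24.4 ± 2.32 CPM. The weakest rise, named after the values were seen, was that of Stat2 (0.60), which carries the interferon signal to the nucleus. Each of the 27 calls held with any single library left out. With log2(TPM + 1), 24 members rose, with a median of 1.98. Counts of type I interferon transcripts themselves were 1 in each shCtrl library and 0 in each shUSP8 library, below what these depths can compare.

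Genes of undifferentiated macrophages and monocytes, listed together with repressors of osteoclast formation expressed there, rose as a group. Of 25 members tested, 17 rose and 3 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.93 (camera adjusted p = 2.79e-08; adjusted p = 0.257 with an estimated correlation). Cd14, a coreceptor for lipopolysaccharide, rose from 122.5 ± 2.24 to 401.9 ± 15.6 CPM (log2 fold change 1.71, SE 0.05). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 1.77 (SE 0.06), Lyz2, a lysozyme, by 1.66 (SE 0.06), and Siglec1, a receptor for sialic acid, by 1.47 (SE 0.07). The 3 members that fell, named after the values were seen, were Cd68, a lysosomal membrane protein (-0.36), Spi1, the transcription factor PU.1 (-0.26), and Csf1r, the receptor for M-CSF (-0.19). The Csf1r call was lost without shCtrl_1 (adjusted p = 0.0561), shCtrl_2 (0.0528) or shUSP8_3 (0.0706), and that of Spi1 with effective-length offsets (0.0583). Beside this group, neutrophil and lymphocyte markers that RAW264.7 cells expressed at low levels moved the same way. The transcription factor Cebpe rose from 3.83 ± 0.333 to 7.91 ± 0.831 CPM, the G-CSF receptor Csf3r from 0.646 ± 0.167 to 2.19 ± 0.308 CPM and the T cell kinase Lck from 1.44 ± 0.171 to 2.64 ± 0.0108 CPM. The calcium-binding protein gene S100a8, at 0.339 CPM in shCtrl, had an adjusted p of 0.0468, lost without shCtrl_1 (0.0798), shCtrl_2 (0.117), shCtrl_3 (0.155), shUSP8_1 (0.159) or shUSP8_3 (0.102). These were the only 3 neutrophil and 1 lymphocyte markers tested of 15 and 18. Of the 10 dendritic cell markers tested, the integrin Itgax (1.43) and the costimulatory receptor Cd40 (1.32) rose, and Cd83 (-0.63) and the chemokine Ccl22 (-1.97) fell (camera adjusted p = 0.9). The 4 stromal markers tested did not pass the test, with Runx2 at 0.14 (adjusted p = 0.473) and Col1a1 at -2.60 (0.11); the Col1a1 value passed without shCtrl_1 (0.0242) or shCtrl_3 (0.0287). Including markers that pass the count filter only with a library left out, 3 stromal markers fell and 1 rose without shCtrl_1, and 1 rose without shCtrl_2 or shUSP8_3.

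Osteoclast genes fell moderately, and the master regulator of the lineage did not pass the test. Of 34 members tested, 21 fell and 2 rose over all genes, and 25 fell and 2 rose adjusted over the list alone. The median log2 fold change was -0.27 (camera adjusted p = 2.07e-06; adjusted p = 0.287 with an estimated correlation). Slc4a2, the chloride-bicarbonate exchanger that osteoclasts need for acid secretion, fell from 941.0 ± 6.67 to 545.0 ± 27.2 CPM (log2 fold change -0.79, SE 0.05). Slc9b2, a sodium-proton exchanger, fell by 0.67 (SE 0.06), and Atp6v0d2, a proton pump subunit needed for cell fusion, by 0.54 (SE 0.05). Mmp9, a gelatinase, fell by 0.46 (SE 0.07), and Acp5, tartrate-resistant acid phosphatase, by 0.34 (SE 0.05). Ctsk, the collagen-degrading cathepsin K, was at -0.15 (SE 0.05) with an adjusted p of 0.0496. Its call was lost without shCtrl_1 (0.122), shCtrl_2 (0.153), shCtrl_3 (0.0839), shUSP8_1 (0.0594), shUSP8_2 (0.0714) or shUSP8_3 (0.118) and with effective-length offsets (0.057). The Ctsk call was also lost with the replicate block (adjusted p = 0.154), library totals (0.268) and log2(TPM + 1) (0.853). Its log2 fold change was -0.08 with library totals and -0.01 on log2(TPM + 1). Nfatc1, the lineage regulator, was at 594.7 ± 66.4 CPM in shCtrl and 600.6 ± 34.6 CPM in shUSP8 (log2 fold change 0.01, SE 0.08, adjusted p = 0.913). The fusion gene Dcstamp was at -0.13 (SE 0.05, adjusted p = 0.0585) and passed with effective-length offsets (-0.18, adjusted p = 0.024). The members that rose were Trem2, a lipid receptor of myeloid cells that aids osteoclast formation (0.72, SE 0.06), and, named after the values were seen, Fos, a partner of Nfatc1 (0.19, lost without shCtrl_3, adjusted p = 0.0748). On log2(TPM + 1), 8 members fell and 3 rose, with a median of -0.13.

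Subunits of the vacuolar proton pump, which acidifies lysosomes and the resorption space, fell nearly throughout. Of 17 members tested, 14 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -0.37; camera adjusted p = 8.76e-07; adjusted p = 0.138 with an estimated correlation). Atp6v1d fell from 395.7 ± 16.4 to 250.6 ± 2.33 CPM, the accessory subunit Atp6ap1 from 683.8 ± 13.1 to 445.4 ± 7.90 CPM and Atp6v1c1 from 612.1 ± 15.1 to 441.5 ± 3.62 CPM. The member that rose, named after the values were seen, was Atp6v0a1 (0.34, SE 0.05), a membrane subunit used in place of the osteoclast form. With effective-length offsets its value was 0.19 and its call was lost (adjusted p = 0.0949). Genes of podosomes and the actin ring, the adhesive structures of resorbing osteoclasts, also fell. Of 29 members, 14 fell and 4 rose over all genes, and 16 fell and 5 rose adjusted over the list alone (median -0.18; camera adjusted p = 0.00924; adjusted p = 0.259 with an estimated correlation). Pstpip1, an adaptor that bends membranes at podosomes, fell from 901 ± 32.8 to 485.7 ± 21.9 CPM, and Gsn, the actin-severing gelsolin, fell by 0.56 (SE 0.06). Plcg2, a phospholipase of immune receptors (0.56, SE 0.05), and Rhou, a small GTPase (0.63, SE 0.07), rose. The other risers, named after the values were seen, were the kinase Ptk2b (0.28) and the adaptor Pxn (0.19), whose call was lost with effective-length offsets (adjusted p = 0.0515). On log2(TPM + 1), 8 proton pump members fell and 1 rose, and 4 podosome members fell and 5 rose.

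Transcripts of the mitochondrial respiratory chain were lower in shUSP8. Among nuclear-encoded subunits, 17 of 36 of complex I fell (21 adjusted over the list alone; median log2 fold change -0.21), 8 of 14 of complexes II and III with cytochrome c (10 over the list alone; -0.24), 6 of 12 of cytochrome c oxidase (6 over the list alone; -0.33) and 10 of 16 of ATP synthase (10 over the list alone; -0.36). Camera gave adjusted p-values of 4.96e-06, 4.83e-04, 0.00121 and 2.64e-04, against adjusted p = 0.603, 0.433, 0.603 and 0.551 with an estimated correlation. Ndufs8, an iron-sulphur subunit of complex I, fell from 159.6 ± 6.15 to 115.0 ± 2.95 CPM (log2 fold change -0.47, SE 0.05, edgeR adjusted p = 1.79e-05). Cycs, cytochrome c, fell by 0.38 (SE 0.05), and Sdha, the flavoprotein of complex II, by 0.24 (SE 0.05); with effective-length offsets Sdha was at -0.16 and lost its call (adjusted p = 0.0737). The oxidase subunits Cox7a2 and Cox4i1 fell by 0.41 (SE 0.07) and 0.30 (SE 0.06). Atp5o, the stalk subunit OSCP, fell by 0.50 (SE 0.07) and the catalytic subunit Atp5b by 0.29 (SE 0.06). The mean fragment length of shUSP8_2 was 368.6 nt, against 301.3 ± 6.44 nt (SD) over the other 5 libraries, and shUSP8_2 had the lowest medians of these 4 lists within shUSP8. Effective-length offsets left 7, 6, 7 and 11 members lower, and log2(TPM + 1) left 3, 2, 2 and 6. On log2(TPM + 1) the median of all genes lay 0.12 higher in shUSP8. Camera with the preset correlation still called the 4 lists lower on that scale (adjusted p = 2.02e-05, 0.00162, 2.56e-04 and 8.9e-06).

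The number of complex I subunits called lower was 29 without shUSP8_1, 12 without shUSP8_2 and 10 without shCtrl_1. It was 7 without shCtrl_2 and 6 without shCtrl_3 or shUSP8_3. Ndufs8, Ndufv1, Ndufb9 and Ndufb6 kept the call with each library left out in turn. Ndufv1 lost it with effective-length offsets (-0.17, adjusted p = 0.171). For complexes II and III the number was 4 without shCtrl_1 or shCtrl_2, 5 without shCtrl_3 and 3 without shUSP8_3. It rose to 9 without shUSP8_1 and 11 without shUSP8_2. For cytochrome c oxidase it was 5 without shCtrl_1 or shCtrl_2, 3 without shCtrl_3, 9 without shUSP8_1 or shUSP8_2 and 4 without shUSP8_3. For ATP synthase it was 6 without shCtrl_1, shCtrl_2 or shCtrl_3, 12 without shUSP8_1, 11 without shUSP8_2 and 7 without shUSP8_3. The median of cytochrome c oxidase lay between -0.44 and -0.21 with a library left out and at -0.12 on log2(TPM + 1).

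**Figure D2:**
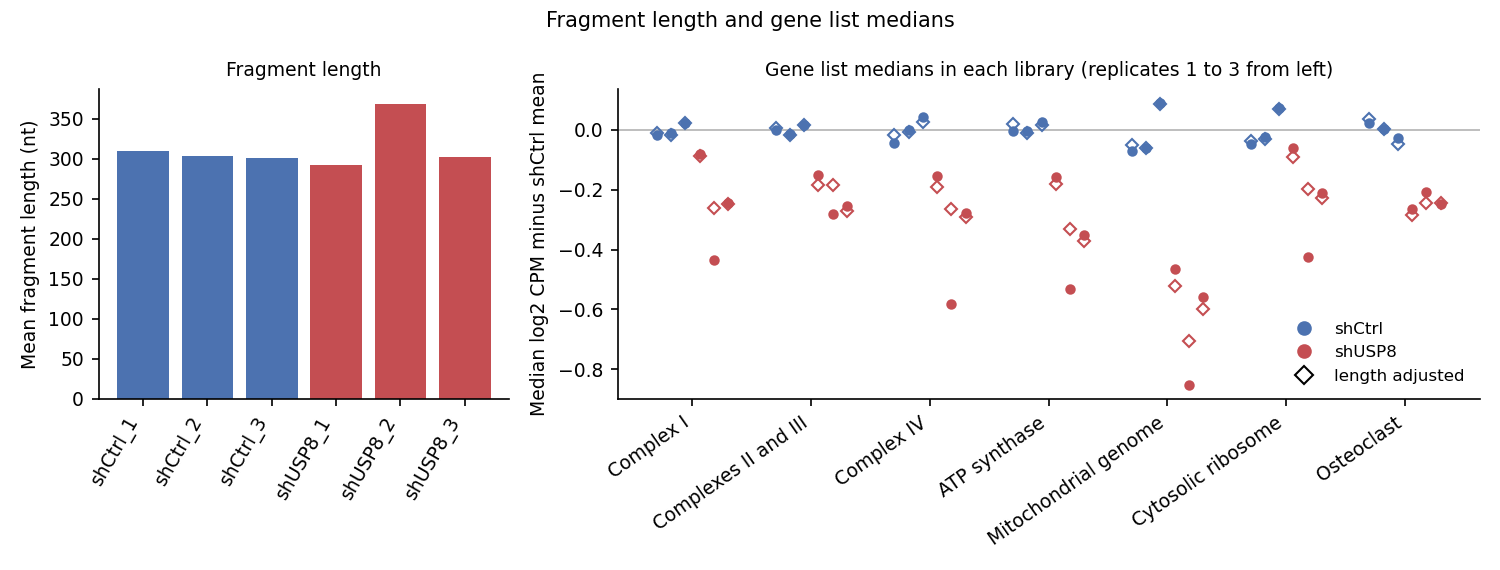
Left, mean fragment length (nt) of each library; right, median log2 CPM of the members of 7 gene lists in each library minus the shCtrl mean, before (filled circles) and after (open diamonds) adjustment for effective length. The bar of shUSP8_2 stands at 368.6 nt, the others lie between 291.5 and 309.3 nt, and the medians of the respiratory lists stay below 0 in every shUSP8 library after adjustment.

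Transcripts of the mitochondrial genome fell too, with 7 of 13 protein-coding genes lower over all genes and 8 adjusted over the list alone (median -0.63; camera adjusted p = 4.42e-05; adjusted p = 0.472 with an estimated correlation). The cytochrome b gene mt-Cytb fell from 6444 ± 415 to 3612 ± 346 CPM (log2 fold change -0.84, SE 0.08), and the complex I genes mt-Nd5, mt-Nd1 and mt-Nd4 fell by 0.66 (SE 0.06), 0.63 (SE 0.08) and 0.63 (SE 0.09). Mitochondrial transcripts took 4.00% ± 0.264 of the counts in shCtrl and 2.91% ± 0.187 in shUSP8 (SD, n = 3 per group; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). On chromosome 1 between 24611535 and 24616197 (GRCm38), 7 nuclear copies share sequence with these genes; with their counts added, the shares were 5.42% ± 0.339 and 3.88% ± 0.336 (exact permutation p = 0.1).

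Enzymes of the citric acid cycle had 10 of 23 members lower and 1 higher, also adjusted over the list alone (median -0.11; camera adjusted p = 0.00184; adjusted p = 0.433 with an estimated correlation). On log2(TPM + 1), 2 fell and 2 rose, with a median of 0.01. Pdhb, a subunit of pyruvate dehydrogenase, fell by 0.49 (SE 0.05), Mdh2, malate dehydrogenase, by 0.36 (SE 0.05) and Fh1, fumarase, by 0.30 (SE 0.05). By contrast, Pcx, the pyruvate carboxylase that refills the cycle, rose by 0.76 (SE 0.07). In fatty acid oxidation, 6 of 17 members fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.116). Etfdh, which passes electrons to ubiquinone, fell by 0.53 (SE 0.05), and Cpt1a, which admits fatty acids to mitochondria, rose by 0.42 (SE 0.06). Of these members, 2 fell and 3 rose on log2(TPM + 1). Glycolytic genes had 13 of 21 members lower and 2 higher (15 and 2 adjusted over the list alone; median -0.20; camera adjusted p = 0.0183; adjusted p = 0.634 with an estimated correlation). Tpi1, triosephosphate isomerase, fell by 0.41 (SE 0.08), Pfkp, a phosphofructokinase, by 0.35 (SE 0.07) and Pgam1, phosphoglycerate mutase, by 0.34 (SE 0.06). Hk3, the hexokinase of myeloid cells, rose by 0.25 (SE 0.05). The other riser, named after the values were seen, was the lactate exporter Slc16a3 (0.19, adjusted p = 0.0496). Its call was lost without shCtrl_1 (0.0532), shCtrl_2 (0.205), shCtrl_3 (0.138), shUSP8_1 (0.104) or shUSP8_2 (0.126) and with effective-length offsets (0.158). The list call was lost without shUSP8_3 (camera adjusted p = 0.0646), and the members called lower numbered 3 without shUSP8_3, 5 without shCtrl_3, 8 without shCtrl_1 and 8 with offsets. The glycolytic calls on log2(TPM + 1) were 2 lower and 2 higher, with a median of -0.08.

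Regulators of mitochondrial number and shape had 4 of 30 members lower and 3 higher, also adjusted over the list alone. Camera did not call the list (adjusted p = 0.264), and fry did (adjusted p = 2.88e-04). Ppargc1b, the coactivator that drives mitochondrial biogenesis in osteoclasts, fell from 77.4 ± 6.47 to 62.1 ± 1.68 CPM (log2 fold change -0.32, SE 0.06, edgeR adjusted p = 0.00236). Mff, a receptor for the fission machinery, fell by 0.30 (SE 0.05), and Mfn2, a fusion GTPase, by 0.22 (SE 0.05). Each of these calls held with any library left out. Mtfr1, a regulator of fission, rose by 0.23, a call lost without shCtrl_2 (adjusted p = 0.0568). The list had 1 riser without shCtrl_2 or shCtrl_3 and 7 fallers without shUSP8_1. With log2(TPM + 1), 3 members rose and none fell (limma-trend). Tfam, which packages mitochondrial DNA, was at -0.03 (SE 0.07, adjusted p = 0.82) and Pink1, a kinase that marks damaged mitochondria, at -0.07 (SE 0.09, adjusted p = 0.594). Of 23 mitophagy genes, 9 fell and 3 rose, also over the list alone (camera adjusted p = 0.13). The receptors Bnip3 and Bnip3l fell by 0.57 (SE 0.09) and 0.38 (SE 0.06). Sqstm1, the cargo receptor p62, rose from 1131 ± 83.1 to 1979 ± 12.2 CPM. The risers numbered 1 without shCtrl_1, shCtrl_2 or shUSP8_3, and the fallers 5 without shCtrl_2. The calls on log2(TPM + 1) were 3 lower and 4 higher, and those with effective-length offsets were 6 lower and 1 higher. The Bnip3l call was lost with effective-length offsets (adjusted p = 0.0954).

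Proteins of the mitochondrial ribosome had 12 of 78 members lower and 2 higher (9 lower adjusted over the list alone; camera adjusted p = 0.13), with Mrpl17 at -0.36 (SE 0.05) and Mrps6 at -0.36 (SE 0.06). That list was called lower without shUSP8_1 (adjusted p = 0.00456), with 22 members lower, and had 6 lower without shUSP8_3 and 7 without shCtrl_1. The risers numbered 1 without shCtrl_1, shCtrl_3 or shUSP8_1 and 5 without shUSP8_2, and no member rose without shCtrl_2 or shUSP8_3. Its calls on log2(TPM + 1) were 2 lower and 4 higher, with a median of 0.12. Mitochondrial import and proteostasis had 2 of 26 members lower and 3 higher (1 and 3 adjusted over the list alone; camera adjusted p = 0.614). The calls of the protease Lonp1 (-0.27) and the translocase subunit Timm50 (0.24) held with each library left out. The protease subunit Afg3l2 (0.18) lost its call without shCtrl_2 (adjusted p = 0.0774), and the import channel Tomm40 (0.18) without shCtrl_2 (0.0644) or shCtrl_3 (0.0734). The list had 1 riser without shCtrl_2, 1 faller without shCtrl_1, shCtrl_2, shCtrl_3 or shUSP8_3, and 5 fallers without shUSP8_1. With log2(TPM + 1), 5 members rose and none fell (limma-trend).

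Antioxidant genes, many of them targets of the transcription factor NRF2, rose strongly. Of 24 members tested, 17 rose and 2 fell, also adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 2.28e-09; adjusted p = 0.259 with an estimated correlation). Cat, which encodes catalase, rose from 80.2 ± 3.62 to 344.5 ± 9.60 CPM (edgeR adjusted p = 6.26e-11). Gclm, a subunit of the enzyme that starts glutathione synthesis, rose by 2.49 (SE 0.07), Srxn1, sulfiredoxin, by 1.54 (SE 0.05). Prdx1, a peroxiredoxin, rose from 368.5 ± 11.2 to 1601 ± 140 CPM. The 2 members that fell, named after the values were seen, were Gpx1, a glutathione peroxidase (-0.29), and Sod1, the cytosolic superoxide dismutase (-0.26, lost without shCtrl_3, adjusted p = 0.0767). Targets of the stress factor ATF4 and its relatives had 13 of 29 members higher (14 adjusted over the list alone; median 0.19; camera adjusted p = 0.0021; adjusted p = 0.639 with an estimated correlation). Slc7a11, the cystine importer that is also in the antioxidant list, rose from 13.6 ± 3.27 to 125.7 ± 13.1 CPM. Atf3, a transcription factor of acute stress, rose from 17.4 ± 1.22 to 79.4 ± 0.718 CPM, Gdf15, a secreted stress signal, by 1.87 (SE 0.26) and Cebpb, a transcription factor of myeloid cells, by 1.00 (SE 0.11). The stress genes Ddit3, Trib3 and Chac1 did not pass (adjusted p = 0.464, 0.833 and 0.282). They stood highest in shCtrl_3, at 53.2, 40.6 and 35.9 CPM, against 16.9 to 26.9, 9.32 to 22.5 and 9.86 to 21.4 CPM in the other 5 libraries. The list median of shCtrl_3 lay 0.24 above the shCtrl mean, higher than those of shUSP8_1 (0.16), shUSP8_2 (0.23) and shUSP8_3 (0.19). Without shCtrl_3 the list had 17 members higher; without shCtrl_2 it had 7, and without shUSP8_3 it had 8. Chaperones of endoplasmic reticulum stress had 2 of 21 members higher, also over the list alone (camera adjusted p = 0.288). The call of the disulphide isomerase Pdia6 (0.32, SE 0.05) held with each library left out, and that of the chaperone Hyou1 (0.23) was lost without shCtrl_1 (adjusted p = 0.0611) or shCtrl_2 (0.0515) and with effective-length offsets (0.0702). The risers numbered 5 without shCtrl_3 and 8 on log2(TPM + 1).

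Lysosomal genes moved both ways, with 15 of 34 members higher and 8 lower (17 and 10 adjusted over the list alone; camera adjusted p = 0.0972). Lipa, lysosomal acid lipase, rose from 219.2 ± 4.83 to 436.1 ± 21.3 CPM, and the cathepsins Ctsl, Ctsc and Ctsd rose by 0.85 (SE 0.06), 0.84 (SE 0.07) and 0.65 (SE 0.06). The lysosomal calls on log2(TPM + 1) were 19 higher and 4 lower. In the ESCRT machinery and endosomal sorting, where USP8 acts, 7 of 38 members rose and 9 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.199). Hgs, the ESCRT-0 subunit that binds ubiquitinated receptors, rose by 0.31 (SE 0.05) and its partner Stam2 by 0.25 (SE 0.05). Rab5b, a GTPase of early endosomes, fell by 0.31 (SE 0.05) and Chmp1b, an ESCRT-III subunit, by 0.31 (SE 0.05). The risers numbered 3 without shCtrl_1 and the fallers 5 without shCtrl_1 and 4 without shCtrl_2 or shUSP8_3. On log2(TPM + 1) 6 rose and none fell (limma-trend), and with effective-length offsets the Stam2 call was lost (adjusted p = 0.0559). Core autophagy genes had 3 of 30 members higher and 6 lower, also over the list alone (camera adjusted p = 0.674). Atg13, a subunit of the initiating kinase complex, rose by 0.70 (SE 0.05). Map1lc3a and Map1lc3b, which coat autophagosomes, fell by 0.49 (SE 0.10) and 0.26 (SE 0.05). The Map1lc3b call was lost with effective-length offsets (adjusted p = 0.0745), and on log2(TPM + 1), 4 autophagy members rose and 2 fell. Among 36 other ubiquitin-specific proteases, 4 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.404). The calls of Usp18, of Usp10, which acts on p53 (0.45, SE 0.07), and of Usp11, a nuclear enzyme (-0.75, SE 0.11), held with each library left out. Usp5 (0.19), which recycles free ubiquitin chains, lost its call without shCtrl_2 (adjusted p = 0.0505) or shCtrl_3 (0.0551) and with effective-length offsets (0.0739). The family had 2 risers without shCtrl_2, 8 without shUSP8_1 and 2 fallers without shCtrl_2 or shUSP8_2, and on log2(TPM + 1) 6 rose and none fell (limma-trend).

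Targets of hypoxia-inducible factors fell, with 12 of 20 members lower and 2 higher, also adjusted over the list alone (median -0.33; camera adjusted p = 0.0071; adjusted p = 0.618 with an estimated correlation). Bhlhe40, a circadian and hypoxia-induced repressor, fell by 0.45 (SE 0.05), Egln1, the prolyl hydroxylase that marks these factors for decay, by 0.49 (SE 0.07) and Mxi1, an antagonist of MYC, by 0.39 (SE 0.06). Car12, a carbonic anhydrase, rose by 1.48 (SE 0.13). The other riser, named after the values were seen, was the collagen prolyl hydroxylase P4ha2 (0.71), lost without shCtrl_2 (adjusted p = 0.0957), shCtrl_3 (0.0736) or shUSP8_2 (0.0798) and at 1.07 with effective-length offsets. Hypoxia members on log2(TPM + 1) were 5 lower and 2 higher. Cytosolic ribosomal protein genes fell by small amounts, with 19 of 55 members lower, also over the list alone (median -0.22; camera adjusted p = 1.71e-06; adjusted p = 0.603 with an estimated correlation). Rpl7 fell by 0.34 (SE 0.05), Rps15 by 0.42 (SE 0.08), Rps24 by 0.45 (SE 0.09) and Rpl3 by 0.33 (SE 0.07). These families have many processed copies, so their counts are uncertain. The members called lower numbered 34 without shUSP8_1, 17 without shUSP8_2, 10 without shCtrl_1 and 7 without shCtrl_2, shCtrl_3 or shUSP8_3. They numbered 14 with effective-length offsets and 3 on log2(TPM + 1). The list median was lowest in shUSP8_2, the library with the longest fragments. The median log2 fold change of the list lay between -0.31 and -0.13 with a library left out. On log2(TPM + 1) it was -0.05, against 0.12 over all genes.

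Inflammatory genes were split, with 11 of 26 members higher and 4 lower, also adjusted over the list alone (median 0.09; camera adjusted p = 0.0441; adjusted p = 0.287 with an estimated correlation). Tnfaip2, induced by tumour necrosis factor, rose from 209.8 ± 5.50 to 363.6 ± 3.08 CPM. Ier3, an immediate early survival gene, rose by 1.01 (SE 0.08), Nos2, the inducible nitric oxide synthase, by 1.63 (SE 0.14), and the chemokine Ccl5 from 0.204 ± 0.0894 to 3.97 ± 0.801 CPM. The 4 members that fell, named after the values were seen, were the chemokines Ccl7 (-1.66) and Ccl9 (-0.56), the NF-kB subunit Rel (-0.38) and the adhesion receptor Cd44 (-0.26). The list call was lost without shCtrl_1 (camera adjusted p = 0.0667), shCtrl_3 (0.0514) or shUSP8_1 (0.0593). Immediate early and heat shock genes, a sign of handling, had 9 of 20 members higher and 4 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.136). Dusp1, a phosphatase of stress kinases, rose by 1.53 (SE 0.07) and Egr1, a growth-induced transcription factor, by 0.54 (SE 0.06), and its relative Egr3 fell by 1.18 (SE 0.12). The fallers numbered 2 without shCtrl_3 and 1 on log2(TPM + 1). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had 3 of 10 members lower, also over the list alone (median -0.27; camera adjusted p = 0.0344; adjusted p = 0.287 with an estimated correlation). Among them were the linker histones H1f2 (-0.89, SE 0.05) and H1f3 (-1.22, SE 0.10). The other, H2bc4 (-0.27), was lost without shCtrl_3 (adjusted p = 0.0536) or shUSP8_3 (0.0571) and with effective-length offsets (0.0684). The list call was lost without shCtrl_1 (0.0505), shCtrl_3 (0.065) or shUSP8_1 (0.0516) and with camera on ranks (0.0688).

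Cell cycle genes showed no list call. Of 32 S phase genes, 2 rose and 1 fell over all genes (camera adjusted p = 0.9), and the count adjusted over the list alone held none of them. The replication factor Gins2 (0.25) lost its call without shCtrl_3 (adjusted p = 0.0795) and with effective-length offsets (0.122). Fen1, a flap endonuclease (0.20), lost it without shCtrl_2 (0.0684), shCtrl_3 (0.129), shUSP8_1 (0.0574) or shUSP8_3 (0.0855) and with offsets (0.0868). Of 32 genes of G2 and mitosis, the cyclin Ccnb2 (-0.45, SE 0.08), the topoisomerase Top2a (-0.23, SE 0.05) and the spindle protein Nusap1 (-0.30, SE 0.07) fell, also adjusted over the list alone (camera adjusted p = 0.832). The kinase Plk1 (0.30) rose over all genes. Its call was lost without shCtrl_2 (0.112), shCtrl_3 (0.117), shUSP8_1 (0.0702), shUSP8_2 (0.0538) or shUSP8_3 (0.064) and with offsets (0.0796). The risers numbered 3 without shCtrl_1 and 2 without shUSP8_3, and on log2(TPM + 1) 4 rose and none fell (limma-trend). Targets of p53 had 8 of 25 members lower and 4 higher (8 and 5 adjusted over the list alone; camera adjusted p = 0.288), with Polk, a translesion polymerase, at -0.70 (SE 0.07) and Plk2, a kinase induced by DNA damage, at 0.79 (SE 0.08). The p53 calls on log2(TPM + 1) were 4 lower and 6 higher. Cholesterol synthesis had 4 of 23 members higher and 1 lower, also over the list alone (camera adjusted p = 0.404). The late-step enzymes Dhcr7 (0.44, SE 0.09) and Hsd17b7 (0.30, SE 0.07) held with each library left out. Hmgcs1, an early enzyme (0.17), lost its call without shCtrl_2 (adjusted p = 0.0686), shCtrl_3 (0.0666) or shUSP8_3 (0.0563). Of the runs with a library left out, the faller passed only in that without shUSP8_1. On log2(TPM + 1) 7 rose and none fell (limma-trend), with a median of all genes of 0.12 on that scale. Camera did not call the list there (adjusted p = 0.154).

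**Figure D3:**
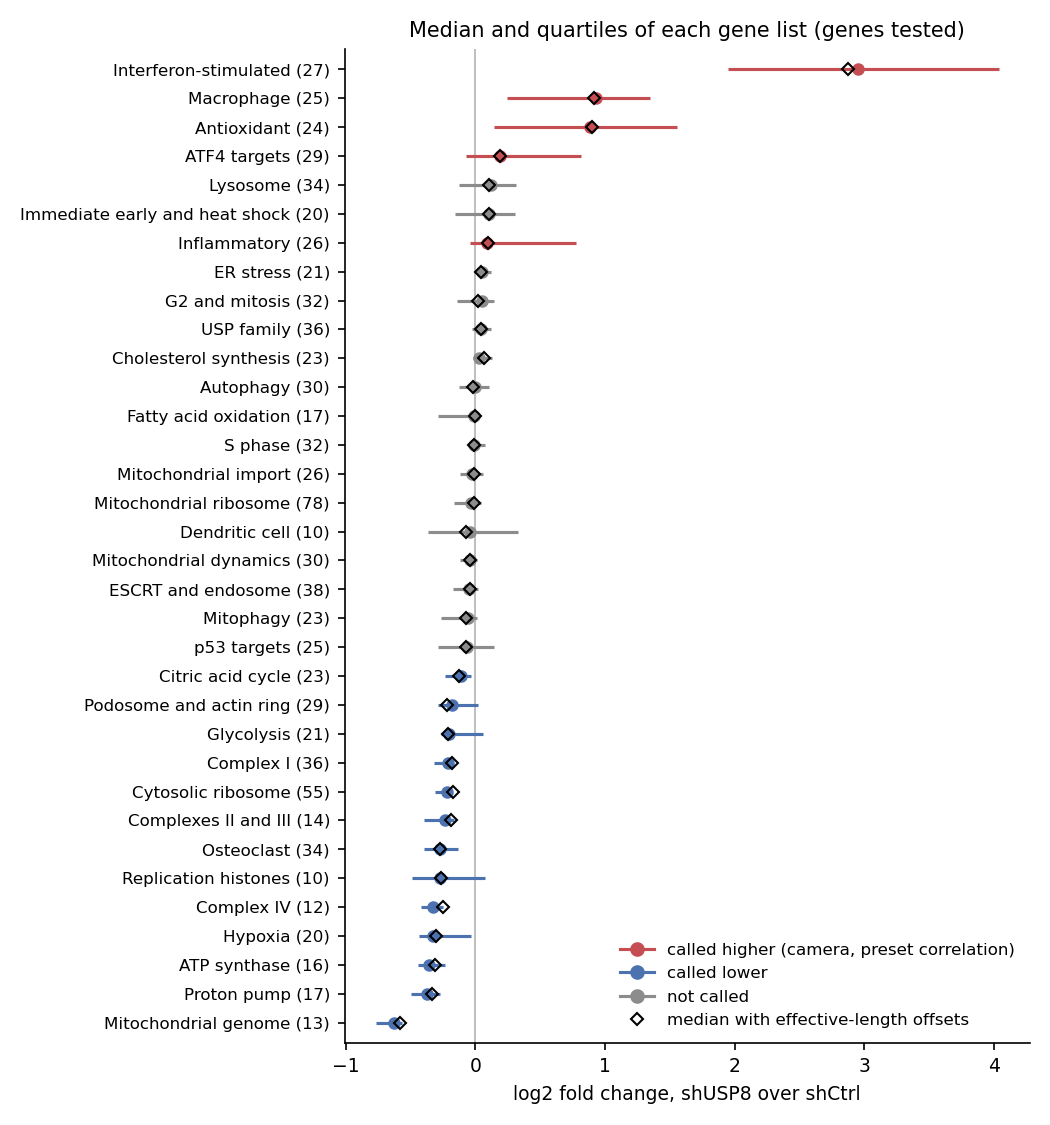
Median (circle) and quartiles (line) of the log2 fold change, shUSP8 over shCtrl, over the tested members of each of 34 gene lists, with the median after effective-length offsets as an open diamond; the number tested is in brackets. The interferon-stimulated list lies at 2.95, the mitochondrial genome at -0.63, and colours mark lists called by camera with the preset correlation.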

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

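The edgeR test called 4077 genes, 665 of them changed at least 2-fold, and 18 lists, and some of these counts depended on the settings. On log2(TPM + 1) 2706 genes passed and 373 changed at least 2-fold; log2(TPM + 0.1) gave 2682 genes, and log2(TPM + 1) without a filter gave 1886 and 367. The TPM scale is set by all transcripts together, and the cause of the difference was not tested. A filter of CPM above 1 in all libraries left 319 genes changed at least 2-fold. For genes changed between shUSP8 and shCtrl, adjusted p under 0.01 gave 2521. For genes changed at least 2-fold between shUSP8 and shCtrl, glmTreat against a fold change of 1.2 in place of that limit gave 1459. Camera with an estimated correlation called 0 lists (smallest adjusted p = 0.138, with 5 lists at unadjusted p under 0.05), fry called 15 and camera on ranks 16. Fry asks whether the members of a list change at all. Camera asks whether they change differently from other genes, so the calls differ in meaning. Of the lists that camera called with the preset correlation, fry did not call complex I (adjusted p = 0.0665), cytochrome c oxidase (0.0675), ATP synthase (0.0591), glycolysis (0.0964), ATF4 targets (0.0605), hypoxia (0.0895) and the cytosolic ribosome (0.0922). Lists that fry called and camera did not were fatty acid oxidation (0.0429), mitochondrial dynamics (2.88e-04), lysosome (0.00178) and immediate early genes (0.00113). The inflammatory list was not called with library totals (adjusted p = 0.0832), on log2(TPM + 1) (0.0726), with the stricter filter (0.0913) or on ranks (0.0876). With the replicate block, 3711 genes passed, 664 of them at least 2-fold, with 18 lists. With each library left out in turn, 2914 to 4426 genes passed, 637 to 693 of them at least 2-fold, and 16 to 18 lists were called. Effective-length offsets, added after the data were seen, gave 2824 genes, 659 at least 2-fold and 18 lists. DESeq2 called 3250 genes and limma-voom 4074. The log2 fold change of Usp8 stayed between -2.03 and -1.79 in 20 alternatives. Of 158 named genes, 54 had a call that moved in some setting, 43 of them with TPM and 18 with a library left out, and none reversed.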

Other observations

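The genes named first, the zinc finger genes, the X chromosome and the test of a smaller share of osteoclasts were chosen after the results were seen, and these single genes stand for no group. Slc40a1, the iron exporter ferroportin, went from 5.53 ± 0.486 to 68.1 ± 1.95 CPM (log2 fold change 3.62, SE 0.08, edgeR adjusted p = 1.68e-11), and Fth1, the ferritin heavy chain, rose by 1.58 (SE 0.08). Nlrc5, an activator of class I genes, rose by 1.36 (SE 0.09), the immunoproteasome subunit Psmb8 by 1.01 (SE 0.06) and the peptide transporter Tap1 by 0.86 (SE 0.06), whereas Cd74 and H2-Eb1, which serve class II presentation, were not called. Tlr7, a receptor for RNA, rose by 1.08 (SE 0.09), Sting1, an adaptor of DNA sensing, by 0.82 (SE 0.09) and Cgas, a DNA sensor, by 0.49 (SE 0.08). Cebpa, a myeloid transcription factor, rose by 1.34 (SE 0.08), and Tnfrsf11a, which encodes the RANKL receptor, fell by 0.52 (SE 0.06). With effective-length offsets Slc40a1 was at 2.98 and Sting1 at 0.52.

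Zinc finger genes with Zfp symbols fell more often than they rose, 43 against 19 of 308 tested, with a median of -0.11 against -0.005 over all genes (limma camera, unadjusted p = 0.00744, and 0.444 with an estimated correlation). The balance of calls depended on the settings: 5 fell and 21 rose on log2(TPM + 1), and 15 fell and 14 rose without shCtrl_3. On log2(TPM + 1) the median of the Zfp genes was 0.01, against 0.12 over all genes. Camera gave an unadjusted p of 0.00218 on that scale, and 0.405 with an estimated correlation. Without shUSP8_1 the camera p was 0.104, and these genes share sequence, so their counts are uncertain. On the X chromosome 85 of 129 called genes (65.9%) fell, against 1764 of 3937 (44.8%) on autosomes (Fisher exact p = 2.36e-06, with genes not independent).

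Among the 10 ways to split the libraries into 3 and 3, only 1, the real split, gave as many as 4077 genes in edgeR, and the highest other count was 0, with 64 to 240 genes at unadjusted p under 0.05 against 5311. With 10 splits no share under 0.05 can be reached.

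The lower respiratory chain and cytosolic ribosome lists may be partly technical, because the fragments of shUSP8_2 were longer. Their median over 133 members was -0.237, and it was -0.193 with effective-length offsets and -0.173 without shUSP8_2. The members called lower went from 60 to 45 with offsets, but genes called lower over all genes went from 1859 to 1261. That drop is therefore not particular to these lists. Without shUSP8_2 the lists had 12, 11, 9, 11 and 17 members lower, against 17, 8, 6, 10 and 19 with all libraries. The order is complex I, complexes II and III, cytochrome c oxidase, ATP synthase and cytosolic ribosome. By the medians, fragment length could account for part of the fall, and the cause of the rest stays open. On log2(TPM + 1) the median was -0.065, against 0.12 over all genes on that scale.

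The higher macrophage list and lower osteoclast list might reflect fewer osteoclasts in the shUSP8 cultures. The chi-square per degree of freedom of the macrophage members about a common value was 106 (24 degrees of freedom), and 3 members fell. The rise of each member would depend on its own level in both kinds of cell, and the list also holds repressors of osteoclast formation. Unequal changes therefore do not count against a smaller share, which stays open. Offsets left the difference of the medians at 1.19, so fragment length is an unlikely cause.

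The higher interferon list could come from signalling set off by the loss of Usp8, from the hairpin or its vector, or from a difference between sublines. These causes coincide with the groups and could not be tested. Its median was 2.87 with offsets against 2.95 without. The members called lay on 14 chromosomes, so gain of a single region that holds them all is unlikely. The largest median over all genes of these chromosomes was 0.02, which cannot exclude a small gain. A gained region with a regulator of these genes was not tested. Type I interferon transcripts numbered 0 in every shUSP8 library and 1 in every shCtrl library, which leaves their part open.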
